A study of Mus musculus with 10 samples.

How the data were processed

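RNA was measured by bulk sequencing in 10 libraries of mouse splenic CD8+ T cells, 2 from each of 3 Dusp2 conditional knockout (cKO) and 2 floxed control mice, rested or activated with anti-CD3/CD28 beads for 24 h. Per the labels' protocols, total RNA was made into libraries with a stranded mRNA kit. Per the submitters' processing notes, the genome build was mm39 and the tools were Subread, FastQC and MultiQC, with no versions. The aligner's settings, the annotation release and whether counting used the strand are not given in the sources used here, so antisense and overlapping genes and near-identical copies are uncertain. The deposited counts are whole numbers per gene and library, with no normalization found in the values. The deposited FPKM values equal the count scaled by the gene length plus 1 and by the column sum, within a relative deviation of 9.4e-07, so they add no reads and were used only as an alternative. Coordinates are those of the deposited table. The annotation at hand was of another build and was used only to look up the strand of a gene by its identifier. The table held 57010 genes, 24326 of them with no count in any library, 1606 identifiers without a name and 305 sharing a name.

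Genotype, treatment and sex were taken from the characteristics and the library names. The titles of both libraries of cKO mouse 3 conflict with these, and the groups follow the characteristics and library names. Sex coincides with the number at the start of the mouse names (male in control mouse 1 and cKO mice 1 and 2, female in control mouse 2 and cKO mouse 3), so a sex term also stands for whatever that number marks. Mice of a group are separate animals. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 9.23 to 45.99 over genes), so none was counted as a repeat. Library totals were 51203786 to 65135435 counts, so that 3 counts correspond to 0.0461 to 0.0586 CPM. Intervals and floors cover counting error only.

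Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr by group (18966 genes tested), and a robust quasi-likelihood fit with group means plus sex over all 10 libraries, so that the groups share an estimate of the spread. The biological coefficient of variation was 9.14%, with 5 residual degrees of freedom and a median prior of 7.95. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in a comparison count as changed. Comparisons were cKO against control at rest and after activation, activated against rested in each genotype, and the interaction. The design, the lists, the naming rule and the alternatives were fixed before the data were examined, except where stated. Of 31 gene lists, 30 had at least 5 tested members (erythroid and platelet markers did not; their summed level was 30.8 ± 3.4 CPM in rested control and 30.5 ± 3.4 CPM in rested cKO cells, 22.9 ± 3.8 CPM and 21.8 ± 3.6 CPM after activation). They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry (directional) were run beside it. Fry tests whether a list moves 1 way and does not compare it with other genes. Limma 3.58.1 and DESeq2 1.42.0 served for alternatives, and Python 3.11.15 for tables and figures.

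Genes were named by rule: Dusp2; per comparison up to 8 with the highest and 8 with the lowest log2 fold change among changed genes with a mean of at least 5 CPM in a compared group and no overlap between the groups' libraries, leaving out predicted genes and receptor segments; up to 4 members per list by smallest p; and, where fewer than 10 genes passed, the 5 with the smallest p under the same filters. Genes outside the rule (those around Dusp2, those of chromosome 16, Gm4613 and Gbp2-ps) were chosen after their values were seen.

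Rested and activated libraries of an animal pair by design. Their deviations from the group means correlated at 0.36, 0.36, 0.25, 0.15 and 0.33 over the 5 mice, control mice first. With sex removed as well they correlated at -0.18, -0.18, 0.05, -0.02 and -0.42. The control mice mirror each other about their mean, so their equal values are 1 value. Removing sex makes the deviations of the female libraries cancel, so the second set cannot show that pairing is absent. The mouse numbers do not pair control with cKO mice, which are different animals. Alternatives were DESeq2 size factors, no and a stricter low-count filter (5 CPM in 2 libraries), no sex term, a sex effect per state, mouse blocks, DESeq2's Wald test, limma-trend on log2(FPKM + 0.5), fitting only the groups compared, a minimum absolute log2 fold change of 1, and leaving out each mouse. Where this leaves a lone control mouse, it is assumed to vary like the other groups. The sex term stays in these fits, and control mouse 2 and cKO mouse 3 are the only females. Without 1 of them the other alone sets the sex term, so its overall level also drops out of the genotype comparisons. DESeq2's test took all genes with a count and its own filter, so it changes both the test and the genes tested.

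The fits were tested on 18966 simulated genes with the real group means, library sizes and spread and no sex effect. Genes were drawn independently of each other, so the simulated lists held no inter-gene correlation. The list results below therefore cannot decide between the preset and the estimated correlation. With 1 unchanged list per comparison they also do not measure how often camera calls in error. Among genes above 1 CPM, 67, 67 and 66 were shifted by 0.5, 1 and 2 on the log2 scale, equally often up and down, and a list of 25 others was shifted by 0.5. These shifts were recovered in 70.1%, 85.1% and 98.5% of genes for the comparison at rest and in 65.7%, 88.1% and 100% for that after activation. Recovery was 53.7%, 91.0% and 98.5% for activation in control, 70.1%, 95.5% and 98.5% for activation in cKO, and 26.9%, 79.1% and 97.0% for the interaction. Of 18741 unchanged genes, 16, 12, 12, 16 and 8 were called. The adjusted threshold depends on how many genes change, so these recoveries hold for data with about as many changes. The shifted list had camera p of 1.76e-33, 2.3e-25, 1.13e-28, 1.76e-42 and 7.6e-32, and 4.06e-05, 8.34e-05, 6.07e-05, 2.2e-05 and 4.63e-05 with an estimated correlation, while an unchanged list had 0.763, 0.936, 0.764, 0.527 and 0.139.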

Results

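RNA was sequenced from splenic CD8+ T cells of 5 mice. In 3 of them, called cKO here, both copies of Dusp2 were floxed and the E8I-cre transgene was carried, which removes floxed DNA in CD8+ T cells. The other 2, the controls, carried the same floxed Dusp2 without cre. DUSP2 is a nuclear phosphatase that switches off MAP kinases. Each mouse gave 1 library of cells activated for 24 h with anti-CD3/CD28 beads, which stand in for antigen and co-stimulation, and 1 of cells rested for the same time without beads, so there were 10 libraries. They held 51203786 to 65135435 counts each, and 3 counts, the floor used here for a gene at 0, corresponded to between 0.0461 and 0.0586 CPM (counts scaled to library size) in a library. The table held 57010 genes, of which 18966 were tested. By its title, the study asks how DUSP2 acts on the BAF chromatin remodelling complex and on CD8+ T cell effector programming. Values are mean CPM ± SD unless stated, with n = 3 cKO and n = 2 control mice. These CPM are not adjusted for sex, while the log2 fold changes of the fit are. The SE beside a log2 fold change was computed back from the test, as its size over the square root of F. It is not the fit's own standard error and can be too small where a group has few counts.

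Dusp2, the targeted gene (ENSMUSG00000027368; chromosome 2, positions 127178079 to 127180296 in mm39), was lower in every cKO library than in every control library. In rested cells it stood at 26.0 ± 1.9 CPM in cKO and 92.6 ± 6.8 CPM in control, a log2 fold change of -1.82 (SE 0.08). In activated cells it stood at 51.8 ± 5.0 CPM in cKO and 295 ± 4.9 CPM in control, 5.64-fold lower in cKO. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 8.1e-08 at rest and 1.18e-09 after activation. The lowest control library held 87.82 CPM and the highest cKO library 56.32 CPM. The sources used here do not say which part of the gene the floxed allele removes, so the counts left in cKO cells are not a measure of functional transcript. All 10 activation markers chosen for the check, among them Il2ra, Irf4 and Myc on the rising side and Il7r and Klf2 on the falling side, separated every activated from every rested library. Of 6 sex-linked genes, 5 separated the male from the female libraries (not Tsix, which was near the floor). These checks include the 2 libraries of cKO mouse 3, whose titles conflict with their other labels.

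All cKO mice and no control mouse carried cre, so Dusp2 loss and cre itself cannot be told apart in the genotype comparisons. The comparison of rested cells asks what differs with genotype before activation. It gave 8 changed genes, 5 higher and 3 lower in cKO, and 3 of the 5 follow Dusp2 on chromosome 2. Astl, an oocyte metalloendopeptidase, stood at 256 ± 14.9 CPM in cKO cells against 13 counts over both control libraries (log2 fold change 11.13, SE 0.34). Adra2b, an adrenergic receptor gene, stood at 74.6 ± 13.2 CPM against 14 counts (9.26, SE 0.38). Gpat2, a glycerol-phosphate acyltransferase gene of the germ line, stood at 11.2 ± 2.9 CPM against 10 counts (7.06, SE 0.31). By edgeR's quasi-likelihood test their adjusted p were 5.79e-06, 0.000135 and 1.56e-07. On the strand of Dusp2, Astl begins 263 bp past its end, Adra2b 24.8 kb and Gpat2 86.8 kb past it. The next tested gene, Fahd2a, lies on the opposite strand 123 bp beyond Gpat2 and had a log2 fold change of 0.19 (SE 0.14, adjusted p = 1.0). Upstream of Dusp2, Stard7 had -0.31 (SE 0.06, adjusted p = 0.245) and Tmem127 -0.14 (SE 0.06, adjusted p = 1.0). These neighbours were named after their values were seen.

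Among the other changed genes at rest, Cdk5rap1, a mitochondrial tRNA-modifying enzyme gene 27.0 Mb from Dusp2 on the same chromosome, fell from 25.4 ± 0.4 CPM to 14.7 ± 1.6 CPM (log2 fold change -0.78, SE 0.11, adjusted p = 0.0154). The rest fall outside the naming rule and were chosen after their values were seen. The long non-coding RNA genes 1810053B23Rik and Gm30695 lie on the minus strand of chromosome 16, within 144.6 kb (93139392 to 93283962), together with 1700029J03Rik. At rest 1810053B23Rik had 156 counts over 3 cKO libraries and 1 over 2 control libraries, a ratio of 111 after scaling by library totals (exact 95% interval 19.6 to 4400, counting error only). Gm30695 had 82 counts in cKO and 0 in control, at least 19.4-fold higher, taking 3 counts over the control group as the floor. By edgeR's quasi-likelihood test the adjusted p was 0.00208 for 1810053B23Rik and 0.0234 for Gm30695. For 1700029J03Rik, at 109 against 3 counts (ratio 25.8, interval 8.6 to 127), it was 0.182. Gm4613, a processed pseudogene whose reads can be shared with its parent gene, fell from 5.82 ± 0.73 CPM to 1.84 ± 0.21 CPM (adjusted p = 0.00186). Control mouse 2 and cKO mouse 3 were the only females. Leaving out 1 of them also took the other's overall level out of the sex-adjusted genotype comparison, here and below. Without control mouse 1 the call ended for Cdk5rap1 (adjusted p = 0.193) and Gm30695 (0.0671), without control mouse 2 for Gm30695 (0.163), without cKO mouse 1 for Cdk5rap1 (0.297), Gm30695 (0.321) and Gm4613 (0.0657), and without cKO mouse 3 for 1810053B23Rik (0.0839) and Gm30695 (0.41). The total became 15 without control mouse 1 and 25 without cKO mouse 2.

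**Figure D1:**
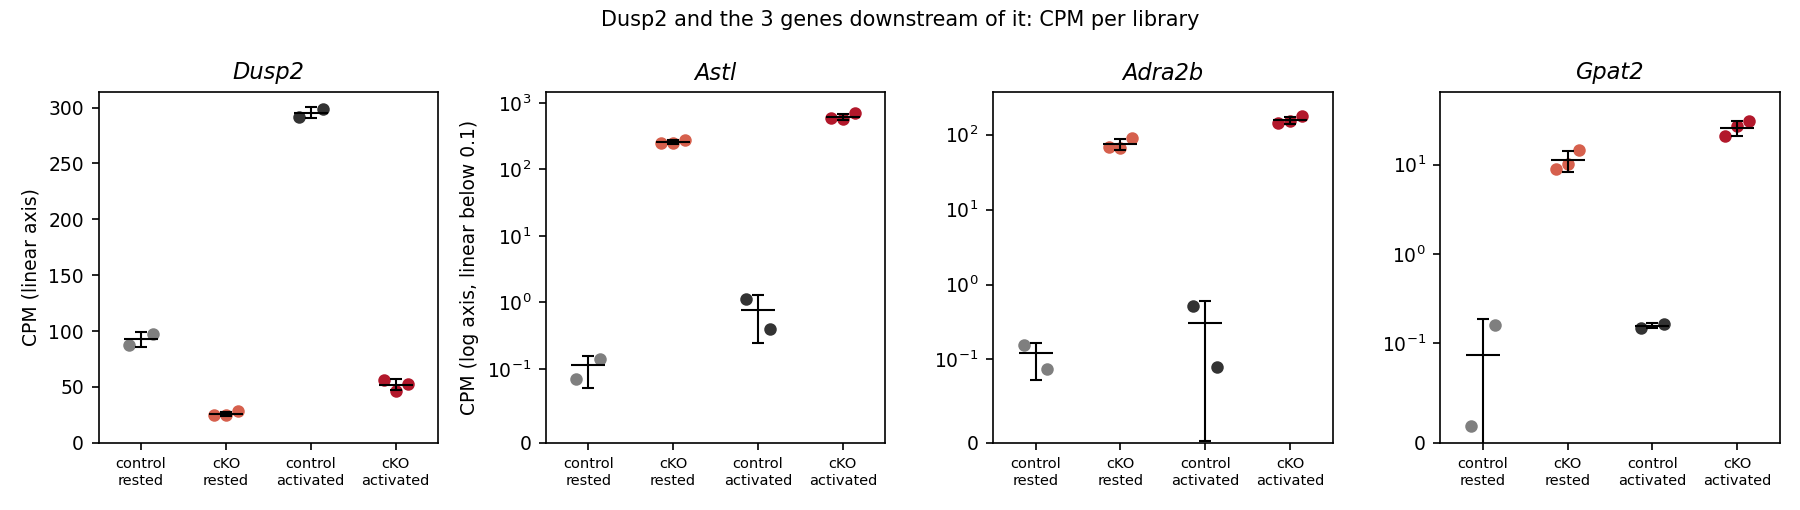
CPM of Dusp2 (linear axis) and of the 3 genes that follow it, Astl, Adra2b and Gpat2 (log axis, linear below 0.1), in each of the 10 libraries. Points are libraries, horizontal bars the group means and whiskers 1 SD; every cKO library lies below every control library for Dusp2 and above it for the 3 genes.

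**Figure D2:**
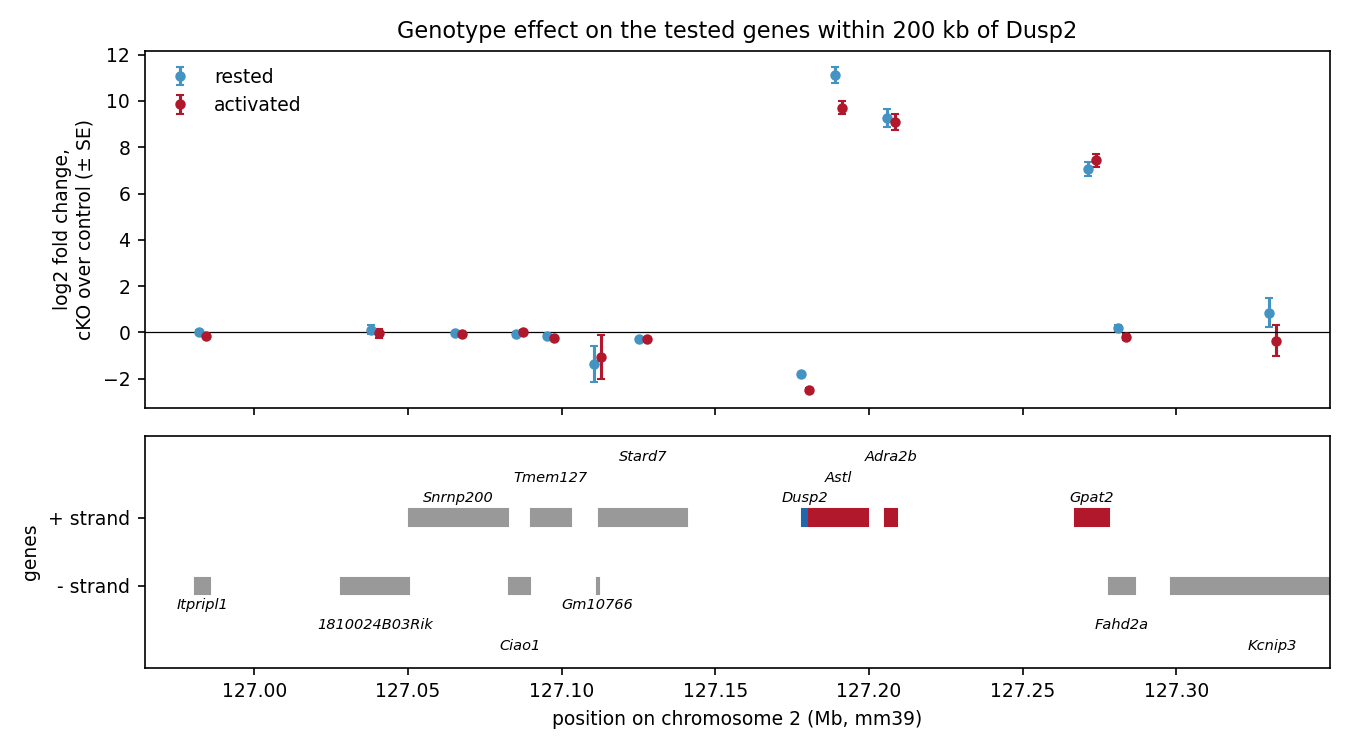
Fitted log2 fold changes (cKO over control, bars 1 SE computed back from the F-test) of the 13 tested genes within 200 kb of Dusp2 on chromosome 2 (mm39 position in Mb), above the extent of each gene on its strand. Dusp2 is drawn in blue and the genes higher in cKO cells, which lie downstream on the same strand, in red.

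Among gene groups in rested cells, effector transcription factors, cytotoxic molecules and cytokines lay somewhat higher in cKO cells, and in these groups no single gene passed the test over all genes. Of 15 effector transcription factors tested 12 had a positive log2 fold change (median 0.26), and 2 passed when adjusted over the list alone, Zeb2 (0.91, SE 0.23) and Irf4 (0.53, SE 0.14). Of 20 cytotoxic molecules 17 were positive (median 0.32) and 0 passed when adjusted over the list alone. Klrg1 was at 0.52 ± 0.45 CPM against 0.174 ± 0.004 CPM in control. Of 18 cytokines and chemokines 15 were positive (median 0.40), again with 0 adjusted over the list alone. The chemokine Ccl5 was at 232 ± 112 CPM in cKO and 132 ± 105 CPM in control. Camera with its preset correlation called these 3 lists (adjusted p = 8.85e-05, 0.0064 and 0.00482), and with an estimated correlation none was called (adjusted p = 0.474, 0.326 and 0.235). Markers of NK and innate-like lymphocytes moved with them: 13 of 18 were positive (median 0.57, 0 passing over all genes or adjusted over the list alone, camera adjusted p = 0.0064, and adjusted p = 0.235 with an estimated correlation), and their summed level was 53.2 ± 12.7 CPM in cKO against 35.7 ± 12.8 CPM in control. By mouse this sum was 67.6, 48.2 and, in the female, 43.8 CPM in cKO. In control it was 44.8 and, in the female, 26.7 CPM. Klre1, an NK receptor gene, was at 2.51 ± 1.31 CPM against 1.11 ± 0.52 CPM. Without cKO mouse 2 Ccl5 (adjusted p = 0.018) and Eomes (0.00236) passed over all genes as higher in cKO. Camera's call ended for cytotoxic molecules without control mouse 2 (adjusted p = 0.277) and without cKO mouse 3 (0.0512), and for the NK list likewise (0.201 and 0.118).

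Camera also called 5 further lists as higher at rest. They were apoptosis and p53 genes (median 0.06), inhibitory receptors and exhaustion genes (0.20), CD4 and regulatory T cell markers (0.20), glycolysis genes (0.08) and NF-kB target genes (0.07). Their adjusted p were 0.0143, 0.0143, 0.0064, 0.0421 and 0.0421, and with an estimated correlation the adjusted p were 0.235, 0.708, 0.293, 0.767 and 0.293. Over all genes 0 members of these 5 lists passed by edgeR's quasi-likelihood test. Adjusted over the list alone, Cdkn1a, a cell cycle inhibitor (0.64, SE 0.11), and Phlda3, a p53 target (1.28, SE 0.26), passed among 25 apoptosis genes. Nr4a1, a transcription factor induced by T cell receptor signals (0.62, SE 0.12), passed among 23 inhibitory receptor and exhaustion genes. Cd4 passed among 13 CD4 and regulatory T cell markers, at 0.893 ± 0.286 CPM against 0.243 ± 0.118 CPM. The 13 mitochondrially encoded genes lay lower (median -0.07, 1 positive, camera adjusted p = 0.0064, adjusted p = 0.767 with an estimated correlation). Camera's calls of these 6 lists ended without several of the mice. Without control mouse 1 the exhaustion (adjusted p = 0.0651), apoptosis (0.139) and NF-kB lists (0.0651) were lost, and without control mouse 2 the exhaustion (0.139), glycolysis (0.463, then lower), apoptosis (0.152), NF-kB (0.463) and CD4 lists (0.201). Without cKO mouse 1 the exhaustion (0.288), glycolysis (0.06) and NF-kB lists (0.0565) were lost, without cKO mouse 2 the glycolysis list (0.142), and without cKO mouse 3 the glycolysis (0.118), apoptosis (0.226), NF-kB (0.581), CD4 (0.118) and mitochondrial lists (0.845). In all 10 of the 30 lists tested were called at rest, while fry called 0. Without cKO mouse 3 the number called was 6, which includes lists that are not among the 10.

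The comparison of activated cells asks what differs with genotype once the cells have been stimulated. It also gave 8 changed genes, 5 higher and 3 lower. The 5 higher genes were the 5 of the rested cells, against 0.00132 shared by chance, and 2 of the 3 lower genes, Dusp2 and Cdk5rap1, were shared as well; both comparisons used the same mice. Astl reached 619 ± 63.5 CPM in activated cKO cells (log2 fold change 9.72, SE 0.28), Adra2b 157 ± 17.0 CPM (9.09, SE 0.34) and Gpat2 25.9 ± 4.9 CPM (7.44, SE 0.27). In the 2 activated control libraries they had 93, 37 and 20 counts. Their adjusted p were 3.32e-06, 6.03e-05 and 1.79e-08 by edgeR's quasi-likelihood test. When only the activated libraries were fitted, the calls for Astl (adjusted p = 0.101) and Adra2b (0.165) ended.

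Cdk5rap1 fell from 24.5 ± 2.2 CPM to 13.4 ± 1.3 CPM in activated cells (log2 fold change -0.86, SE 0.11, adjusted p = 0.00673 by edgeR's quasi-likelihood test). The chromosome 16 genes 1810053B23Rik and Gm30695 had 152 and 91 counts over the activated cKO libraries and 0 in control, at least 35.8-fold and 21.4-fold higher (adjusted p = 0.0015 and 0.0183). Their neighbour 1700029J03Rik had 72 counts against 0, at least 16.9-fold higher, with an adjusted p of 0.127. Gbp2-ps, a pseudogene of an interferon-induced GTPase family whose members can share reads, was lower in cKO (adjusted p = 0.0117), but only control mouse 1, at 2.29 CPM, lay above the floor. It was named after its values were seen, as were the chromosome 16 genes. Without control mouse 1 the call ended for Cdk5rap1 (adjusted p = 0.464) and Gm30695 (0.0567), and without control mouse 2 for Gm30695 (0.218). It ended without cKO mouse 1 for Cdk5rap1 (0.0765), Gm30695 (0.291) and Gbp2-ps (0.155), and without cKO mouse 3 for 1810053B23Rik (0.0889) and Gm30695 (0.703). Without cKO mouse 2 the total rose to 49 genes.

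T cell cytokines and chemokines were the group that lay highest in activated cKO cells. Of 18 tested, 15 had a positive log2 fold change (median 0.68), 0 passed over all genes, and 6 passed when adjusted over the list alone, each higher in cKO. Among the 6 were the chemokine genes Ccl9 (9.56 ± 3.39 CPM against 2.77 ± 0.16 CPM, log2 fold change 1.82, SE 0.37), Ccl3 (106 ± 24.9 CPM against 54.1 ± 4.2 CPM, 0.88, SE 0.22) and Ccl5 (74.8 ± 36.9 CPM against 44.0 ± 38.4 CPM, 0.65, SE 0.16). Ccl1 was among them too, at 2.89 ± 3.56 CPM against 0.442 ± 0.271 CPM. Camera called the list (adjusted p = 8.01e-11), and it was called with an estimated correlation (adjusted p = 0.0358) and by fry (adjusted p = 0.0222), the only list of which either held. With an estimated correlation the call ended without any of the 5 mice: adjusted p was 0.298 without control mouse 1, 0.359 without control mouse 2, 0.334 without cKO mouse 1, 0.129 without cKO mouse 2 and 0.274 without cKO mouse 3. NK and innate-like markers moved in the same direction, with 12 of 18 positive (median 0.54) and 79.3 ± 17.8 CPM summed in cKO against 47.7 ± 13.0 CPM in control. With their level as a covariate, added after the data were seen, the cytokine list had a camera adjusted p of 0.00862, and an adjusted p of 0.377 with an estimated correlation. Over all genes Ccl5 passed without cKO mouse 2 (adjusted p = 0.0272) and Ccl9 without control mouse 1 (0.0483).

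Among these NK and innate-like markers, camera's adjusted p was 0.000427 (0.146 with an estimated correlation), and 0.0612 without cKO mouse 3. Over the list alone 3 passed, Klra3 (0.97, SE 0.24), Klre1 (1.05, SE 0.31) and the granzyme gene Gzma (2.48, SE 0.74), and 0 passed over all genes. Cytotoxic molecules lay higher too, with 18 of 20 positive (median 0.39), 0 passing over all genes or adjusted over the list alone, and a camera adjusted p of 5.71e-06 (adjusted p = 0.165 with an estimated correlation). Nkg7 was at 23.9 ± 3.3 CPM against 17.7 ± 0.1 CPM, Serpinb9, an inhibitor of granzyme B, at 38.5 ± 9.7 CPM against 24.4 ± 1.6 CPM, and Gzmb at 4.61 ± 1.28 CPM against 2.90 ± 1.71 CPM. Effector transcription factors as a list were not called (median -0.00, mean 0.15, camera adjusted p = 0.31). Zeb2 passed when adjusted over that list alone, at 12 ± 1.5 CPM against 7.14 ± 1.71 CPM (0.72, SE 0.16). Eomes, counted in both the NK list and this list, was at 60.5 ± 16.3 CPM against 34.1 ± 9.6 CPM. Without cKO mouse 2 Eomes (adjusted p = 0.00246), Serpinb9 (0.0342), Nkg7 (0.0395) and Zeb2 (0.0422) passed over all genes, each higher in cKO.

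Growth and cell cycle lists lay slightly higher in activated cKO cells, and 0 of their members passed over all genes or adjusted over the list alone. They were DNA replication genes (38 of 39 positive, median 0.22), mitosis genes (35 of 37, 0.31), oxidative phosphorylation genes (32 of 34, 0.08), glycolysis genes (19 of 22, 0.14) and ribosome biogenesis genes (26 of 30, 0.08). Camera's adjusted p were 8.01e-11, 1.79e-08, 5.71e-06, 0.0084 and 0.00849, and with an estimated correlation the adjusted p were 0.619, 0.365, 0.667, 0.667 and 0.737. Heat shock and stress genes, a list measured as a sign of sample quality, lay higher beside them (16 of 18 positive, median 0.14, camera adjusted p = 0.00812, adjusted p = 0.619 with an estimated correlation), also with 0 passing. Cdk1 was at 4.81 ± 1.25 CPM against 3.17 ± 1.05 CPM, and Cdc6, which loads the replicative helicase, at 8.91 ± 2.81 CPM against 6.75 ± 2.26 CPM. Naive and memory genes lay lower (7 of 28 positive, median -0.09, camera adjusted p = 0.0144, adjusted p = 0.667 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Klf3 was at 152 ± 20.5 CPM against 176 ± 12.3 CPM. Of the homing receptors, Itga4 (-0.35, SE 0.08) and Ccr4 (-0.84, SE 0.21) passed as lower when adjusted over their list alone, with adjusted p of 0.481 and 0.516 over all genes by edgeR's quasi-likelihood test. S1pr5 passed as higher over that list, at 0.235 ± 0.039 CPM against 0.0235 ± 0.0095 CPM (adjusted p = 0.516 over all genes). Its control level lay below the floor of 3 counts (0.0516 and 0.0461 CPM in the activated control libraries), so the size of the difference is uncertain. The homing receptor list was not called (15 of 26 positive, camera adjusted p = 0.974). Without cKO mouse 2 Ccr4 passed over all genes as lower (adjusted p = 0.026). Camera's call ended without control mouse 1 for oxidative phosphorylation (adjusted p = 0.26) and ribosome biogenesis (0.902, then lower), without control mouse 2 for naive and memory (0.102) and heat shock genes (0.114), and without cKO mouse 1 for ribosome biogenesis (0.146). Without cKO mouse 3 it ended for naive and memory (0.795), glycolysis (0.795), ribosome biogenesis (0.551) and heat shock genes (0.623). In all 10 lists were called in activated cells. Without cKO mouse 3 the number called was 6, not all of them among the 10.

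**Figure D3:**
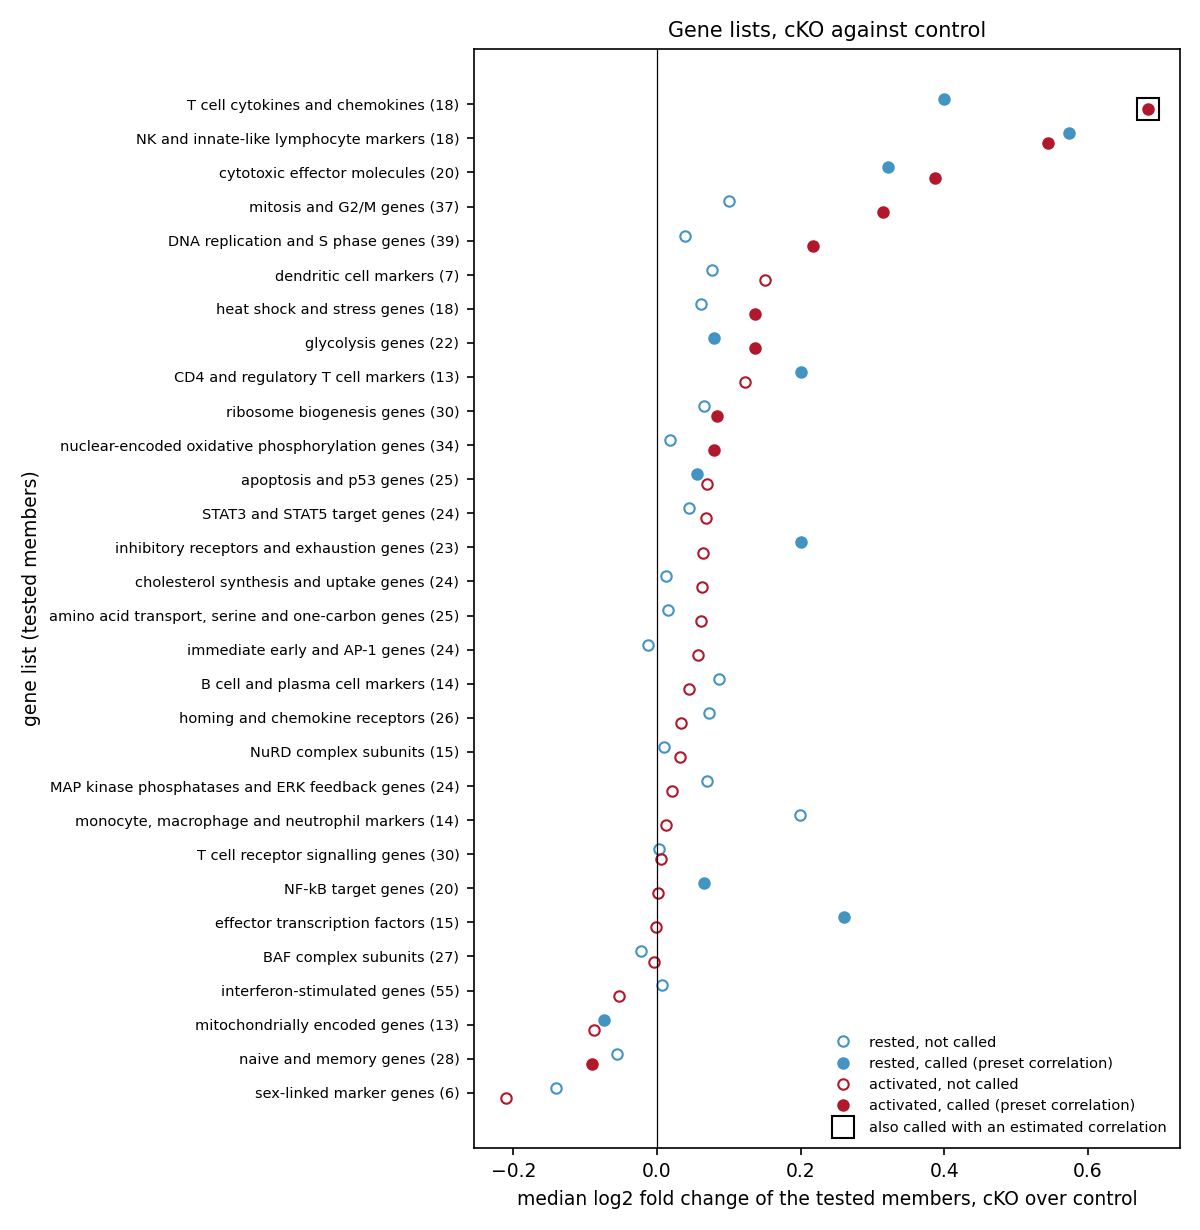
Median log2 fold change (cKO over control) of each of the 30 gene lists, with tested members in brackets, in rested (blue) and activated (red) cells. Filled points are lists called by camera with its preset correlation, and the square marks the cytokine list in activated cells, at 0.68, which was also called with an estimated correlation.

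**Figure D4:**
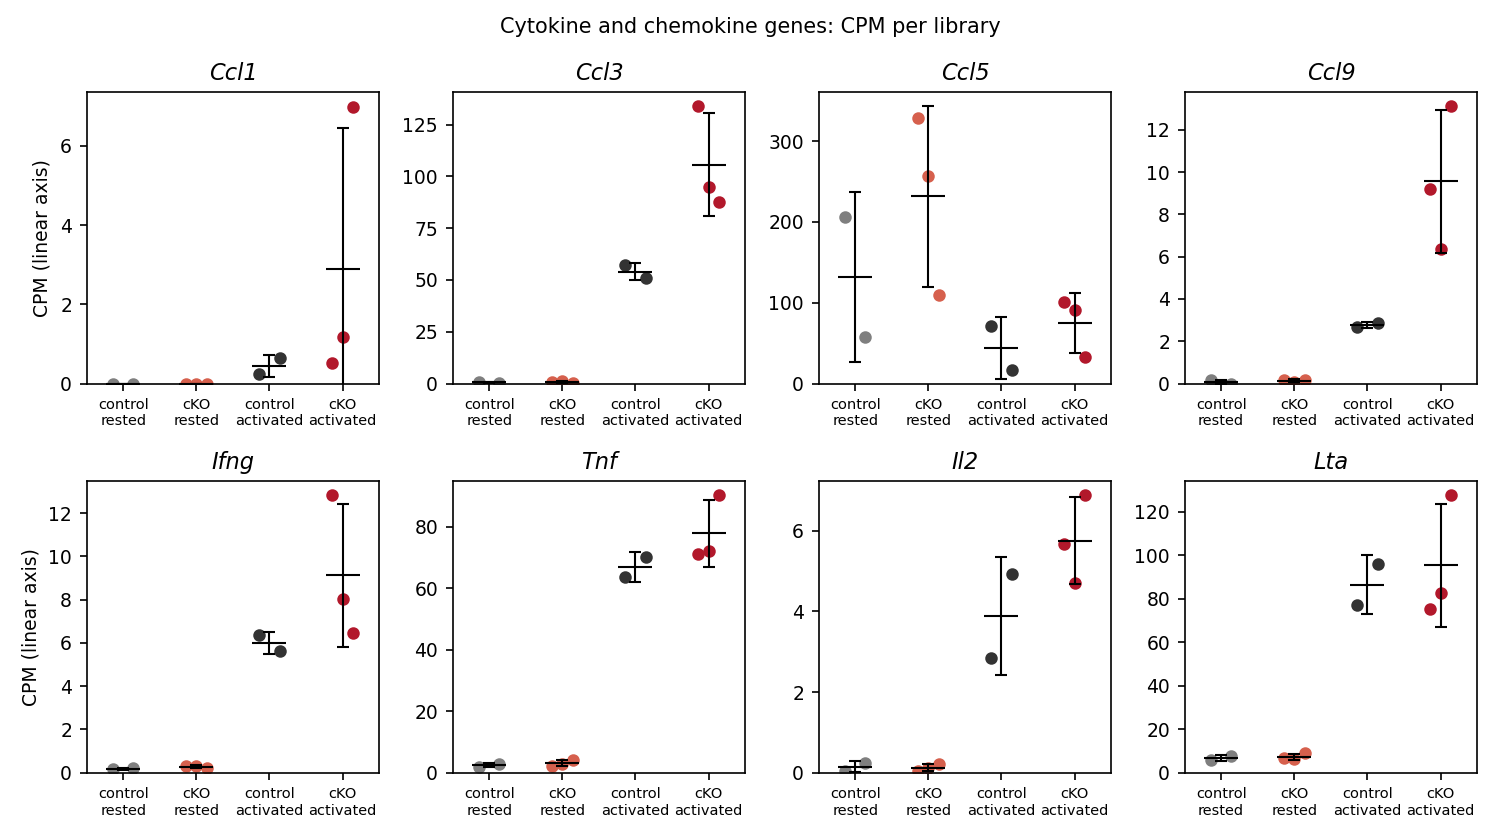
CPM (linear axes) of 8 cytokine and chemokine genes in each library; points are libraries, horizontal bars group means and whiskers 1 SD. Ccl3 and Ccl9 lie higher in every activated cKO library than in the activated control libraries, while Il2 and Lta overlap between the genotypes after activation.

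Transcripts of the BAF subunits were measured because the study concerns that complex. The protein, phosphorylation and assembly of the subunits were not measured. Of 27 tested, 0 differed between genotypes at rest or after activation over all genes or adjusted over the list alone. Their median log2 fold changes were -0.02 and -0.00, and camera's adjusted p were 0.376 and 0.319; at rest the mean (0.06) had the opposite sign. Arid1a, a DNA-binding subunit of the canonical complex, was at 478 ± 14.8 CPM in activated cKO and 528 ± 1.0 CPM in control cells (-0.14, SE 0.06, adjusted p = 0.805 by edgeR's quasi-likelihood test), and Pbrm1, of the polybromo form, at 126 ± 6.3 CPM and 140 ± 4.6 CPM (-0.15, SE 0.06, adjusted p = 0.806). Smarcd1 at rest was at 64.7 ± 1.4 CPM and 68.9 ± 0.4 CPM. Summed over the list, BAF transcripts stood at 3720 ± 55.7 CPM in rested cKO against 3759 ± 2.4 CPM in control, and after activation at 3058 ± 23.5 CPM against 3151 ± 17.6 CPM. Of 15 subunits of NuRD, another remodelling complex, 0 differed in either state, over all genes or adjusted over the list alone, with medians of 0.01 and 0.03. At this depth and n, 70.1% of simulated changes of 0.5 on the log2 scale were recovered at rest and 65.7% after activation. Those simulations held many more changed genes than the 8 called in each real comparison, which eases the adjusted threshold. Recovery here can therefore be lower, and changes of that size in single subunits are not excluded.

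Activation changed the BAF subunits in both genotypes and in both directions. In control cells 7 rose and 15 fell, and in cKO cells 9 rose and 14 fell. Phf10, a subunit of the polybromo form, rose 2.56-fold in control and 2.78-fold in cKO cells, while Smarca2, the alternative ATPase, fell 2.25-fold and 2.38-fold. Bcl11b, a T cell transcription factor that binds the complex, fell 1.97-fold and 2.05-fold, and Bicral fell 1.90-fold and 2.07-fold. By edgeR's quasi-likelihood test the highest adjusted p among these 4 genes was 1.75e-07. Adjusted over the list alone, the counts were 7 and 15 in control and 10 and 14 in cKO. As a list the BAF subunits were not called (medians -0.23 and -0.20, camera adjusted p = 0.144 and 0.147; the mean was 0.02 in control and -0.04 in cKO). Of the NuRD subunits 8 rose and 4 fell in each genotype, also adjusted over the list alone, with Rbbp7 rising 1.96-fold and 2.09-fold and Chd3 falling 1.74-fold and 1.87-fold.

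In control cells activation changed 10631 genes (56.1% of those tested), 5399 of them higher and 5232 lower, and 4136 by at least 2-fold. The nuclear receptor Nr4a1 rose from 2.82 ± 0.83 CPM to 955 ± 77.0 CPM, the transcription factor Irf4 from 5.84 ± 0.30 CPM to 1214 ± 174 CPM, and Il2ra, the alpha chain of the IL-2 receptor, from 1.27 ± 0.46 CPM to 387 ± 44.7 CPM. Their log2 fold changes were 8.42 (SE 0.12), 7.70 (SE 0.17) and 8.25 (SE 0.33), with adjusted p of 4.45e-14, 1.42e-10 and 9.84e-07 by edgeR's quasi-likelihood test. Rgs16, which restrains G protein signals, rose 290-fold, Cd83 252-fold and Bcat1, an enzyme of branched-chain amino acid breakdown, 333-fold. Among genes that fell, the sialyltransferase gene St8sia6 fell 7.06-fold, Itga2 5.76-fold, Ifitm10 5.51-fold and Rflnb 5.05-fold. Without control mouse 2 the total was 6981 genes.

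All 18 cytokines and chemokines passed in control cells, 15 higher and 3 lower, also adjusted over the list alone (median 5.29). Lta rose to 86.4 ± 13.5 CPM, Tnf to 66.9 ± 4.7 CPM, Il2 to 3.88 ± 1.47 CPM and Ifng to 6.356 and 5.645 CPM in the 2 libraries. Of 20 NF-kB targets 18 rose and 1 fell, with Nfkb1 up 4.39-fold. Of 24 immediate early and AP-1 genes 19 rose and 2 fell, with Egr3 up 142-fold and Atf3 163-fold. Of 25 amino acid transport and one-carbon genes 24 rose, with the serine synthesis gene Psat1 up 29.7-fold and the transporter chain Slc3a2 4.35-fold. The counts of these 3 lists did not change when adjusted over the list alone. Of 25 apoptosis and p53 genes 18 rose and 4 fell (19 and 4 adjusted over the list alone), with Cdkn1a up 162-fold, and of 24 STAT3 and STAT5 targets 15 rose and 6 fell, also adjusted over the list alone, with Cish, a feedback inhibitor of cytokine signals, up 17.6-fold. Of 18 heat shock genes 14 rose and 2 fell, also over the list alone, with the chaperone Hspa5 up 4.32-fold. Camera called these 7 lists, and they are the ones called with an estimated correlation (adjusted p = 0.0123, 0.00644, 0.0246, 0.0325, 0.0123, 0.0246 and 0.0447 in the order given).

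Further lists in control cells were called by camera with its preset correlation and not with an estimated one, while fry, which does not compare a list with other genes, called 27 of the 30 lists in each genotype. Of 30 ribosome biogenesis genes 29 rose (30 adjusted over the list alone), with Nop58 up 5.13-fold, and of 39 DNA replication genes 31 rose (31 higher and 1 lower over the list alone), with Pcna up 2.13-fold. Of 37 mitosis genes 29 rose and 6 fell, also over the list alone, with Top2a up 14.2-fold. Camera's adjusted p were 8.4e-36, 1.73e-06 and 0.000206, and with an estimated correlation the adjusted p were 0.107, 0.404 and 0.303. Of 24 MAP kinase phosphatases and ERK feedback genes 17 rose and 3 fell (18 and 3 over the list alone; adjusted p = 0.0946 with an estimated correlation), with Spry1 up 150-fold and Dusp6 4.30-fold. Naive and memory genes went the other way, with 18 lower and 10 higher, also over the list alone (median -1.06, camera adjusted p = 4.13e-06, adjusted p = 0.187 with an estimated correlation). Il6ra fell 3.42-fold, Klf3 3.06-fold and Slamf6 2.18-fold. Of 26 homing receptors 11 fell and 7 rose, also over the list alone (median -0.60, mean 0.14, camera lower with adjusted p = 0.0136, adjusted p = 0.303 with an estimated correlation), with Itga4 down 2.88-fold. Of 20 cytotoxic molecules 7 rose and 4 fell, also over the list alone, and the list was not called (adjusted p = 0.589). Gzmb rose 9.90-fold to only 2.90 ± 1.71 CPM, Srgn rose 3.01-fold and Klrd1 fell 3.00-fold. Of 18 NK and innate-like markers 5 rose and 3 fell, also over the list alone. Klra3 rose 2.19-fold and Klrb1c fell 2.92-fold at under 1 CPM, both calls ending without control mouse 1 (adjusted p = 0.0957 and 0.307).

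In cKO cells activation changed 12017 genes (63.4%), 5976 higher and 6041 lower, and 4647 by at least 2-fold. Lad1 rose from 0.076 ± 0.039 CPM to 131 ± 28.9 CPM, Nr4a1 from 4.13 ± 0.87 CPM to 907 ± 131 CPM, and Il2ra from 2.04 ± 0.66 CPM to 419 ± 48.8 CPM. Their adjusted p were 3.31e-10, 5.65e-15 and 2.15e-07 by edgeR's quasi-likelihood test. Atf3 rose 284-fold and Irf4 134-fold. Among genes that fell, St8sia6 fell 8.91-fold, Ifitm10 6.52-fold, Gas7 6.29-fold and Depdc1b 6.07-fold. The larger count in cKO than in control comes with 3 mice against 2 and is not by itself a difference between genotypes. Of the genes higher in control cells 5021 (93%) were also higher in cKO cells, where independent lists would share 1700, and of those lower 4953 (94.7%) were also lower, where independent lists would share 1670; 1 gene went opposite ways. These comparisons shared no library. Across the tested genes, which are not independent replicates, the log2 fold changes of the 2 genotypes had a Pearson r of 0.89, and their median absolute difference was 0.12.

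The same gene groups led in cKO cells. All 18 cytokines and chemokines passed, 15 higher and 3 lower, also adjusted over the list alone, with Lta at 95.3 ± 28.4 CPM, Tnf at 77.8 ± 10.8 CPM, Ifng at 9.12 ± 3.32 CPM and Il2 at 5.75 ± 1.09 CPM. Of 20 NF-kB targets 18 rose and 1 fell, of 24 immediate early genes 21 rose and 2 fell, of 25 amino acid and one-carbon genes 24 rose, of 25 apoptosis and p53 genes 19 rose and 4 fell, and of 24 STAT3 and STAT5 targets 17 rose and 6 fell. Adjusted over the list alone these counts did not change. With an estimated correlation camera called the cytokines and these 5 lists (adjusted p = 0.0283, 0.0073, 0.0283, 0.0414, 0.0223 and 0.0283 in the order given). Of 30 ribosome biogenesis genes 30 rose, also over the list alone, with Gar1 up 5.24-fold (adjusted p = 0.114 with an estimated correlation for the list), and of 18 heat shock genes 16 rose and 2 fell, also over the list alone (0.0542). Naive and memory genes again fell more often than they rose, 18 against 8, also over the list alone (median -1.07, camera adjusted p = 2.71e-06, adjusted p = 0.174 with an estimated correlation), with Il6ra down 3.70-fold.

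The interaction asks whether activation acted differently in cKO cells. By edgeR's quasi-likelihood test 0 genes passed, with a smallest adjusted p of 0.248. An unadjusted p under 0.05 was reached by 519 of the 18966 genes tested, a share below the 0.05 that no difference would give. DESeq2's Wald test, run without the low-count filter (32684 genes tested against 18966), gave 17 genes and limma on FPKM 0. Without the low-count filter edgeR gave 39, and 3 passed without cKO mouse 3. Dusp2 itself came nearest, rising 3.19-fold in control and 2.00-fold in cKO cells (difference in log2 fold change -0.68, SE 0.11, adjusted p = 0.248). Over the alternatives this adjusted p ran from 1.56e-07 without the low-count filter, through 0.000263 with DESeq2, to 1.0. Without the filter the difference was -0.667, so the smaller p came from the fitted spread and not from a larger effect. The T cell receptor response genes Nr4a1 (-0.64, SE 0.14) and Egr3 (-0.64, SE 0.19), the adaptor gene Sh3bp2 (-0.46, SE 0.10) and the p53 target Phlda3 (-1.32, SE 0.30) had an adjusted p of 1.0, and without the low-count filter 3.27e-05, 0.0253, 0.151 and 0.00474 in that order. Adjusted over the list alone, Nr4a1 passed among inhibitory receptor and exhaustion genes, and Phlda3 and Cdkn1a (-0.55, SE 0.13) among apoptosis and p53 genes, each rising less in cKO cells; neither list was called (camera adjusted p = 0.16 and 0.244). For Nr4a1, activated levels were 907 ± 131 CPM in cKO and 955 ± 77.0 CPM in control, against rested levels of 4.13 ± 0.87 CPM and 2.82 ± 0.83 CPM. Camera called 4 lists: DNA replication genes (median 0.16, adjusted p = 0.000973), mitosis genes (0.12, 0.0318) and oxidative phosphorylation genes (0.04, 0.0402) as rising more in cKO cells, and effector transcription factors as rising less (-0.17, 0.0318). With an estimated correlation each had an adjusted p of 0.833, and fry called 0. In these 4 lists 0 genes passed over all genes or adjusted over the list alone. Without control mouse 1 camera no longer called the DNA replication (adjusted p = 0.625, then in the opposite direction), mitosis (0.569) and oxidative phosphorylation lists (0.793), and without control mouse 2 the effector transcription factors (0.345). Without cKO mouse 3 it called none of the 4 (0.843, 0.653, 0.907 and 0.134 in the order given, oxidative phosphorylation then in the opposite direction). Over all lists the number called was 11 without control mouse 2 and 9 without cKO mouse 2. The cytokine list, which lay higher in cKO cells in both states, had a median interaction of 0.02 (camera adjusted p = 0.744).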

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

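The fit with NK marker level as a covariate and the activation marker check on FPKM in place of CPM (10 of 10 markers in both) were chosen after seeing the data; the other alternatives were planned, and the cause of a change was not tested unless stated. Of 2873 values for the 197 named gene and comparison pairs, 2770 kept direction and side of the threshold, 57 newly passed it, 40 no longer did and 6 turned sign. In the activation comparisons 821 of 824 values in control and 795 of 796 in cKO cells kept both. The exceptions were Klra3 (adjusted p = 0.133 without sex and 0.0957 without control mouse 1) and Klrb1c (0.307 without control mouse 1) in control cells, and Gas7 (0.0742 without sex) in cKO cells. DESeq2 size factors changed no named gene. Of those that turned, none had passed the test. With the NK covariate Pfkp at rest went from 0.20 to -0.029, and after activation Rrm2 went from 0.51 to -0.18, Nhp2 from 0.21 to -0.017 and Eomes from 0.75 to -0.16, where Eomes itself makes up 66.2% of the covariate's list (mean over libraries). Gatad2a at rest (0.05) ran from -0.017 without control mouse 1 to 0.081 without cKO mouse 3, and Eno1 after activation went from 0.22 to -0.007 with the mouse number as a block. Limma on FPKM ended the calls at rest and after activation for Cdk5rap1 (adjusted p = 0.24 and 0.271), 1810053B23Rik (0.247 and 0.388) and Gm30695 (0.101 and 0.1). The stricter filter ended Cdk5rap1 at rest (0.06), and Gm30695 was lost after activation with only those libraries fitted (0.0708) and with the number as a block (0.0514), and with the NK covariate at rest (0.249) and after activation (0.42). Gbp2-ps was lost without sex (1.0), with either block (0.905 and 0.222), with DESeq2 (1.0), with limma on FPKM (0.779) and with the NK covariate (1.0), and Gm4613 with the NK covariate (0.153). Of the 57 gains, 34 came without the low-count filter, 10 without cKO mouse 2 and 8 with DESeq2. For Dusp2 at rest the log2 fold change without the filter stayed at -1.82, while edgeR's adjusted p went from 8.1e-08 to 1.22e-134. The fitted spread and not a larger effect gave that p, so calls and counts gained without the filter carry this limit. With DESeq2 Ccl5 (0.000803), Irf4 (0.0354), Nr4a1 (0.00681), Cdkn1a (0.0252) and Phlda3 (0.0124) passed at rest, Ccl5 (0.00203) and Serpinb9 (0.0304) after activation, and Dusp2 in the interaction (0.000263). Without cKO mouse 2 Ly6c2 passed at rest (0.0325) and after activation (0.0296), and with a sex effect per state Nr4a1 at rest (0.019) and Itga4 after activation (0.0187).

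Changed genes at rest (8 in the planned fit) numbered 204 without the low-count filter, 5 with the stricter filter, which tests fewer genes, and 20 with the mouse number as a block. They numbered 46 with DESeq2, which also went without that filter (30233 genes tested), 5 with limma on FPKM, and 7 to 25 leaving out a cKO mouse. After activation (8) they numbered 211, 5, 13, 30 and 4 (3 higher and 1 lower, against 5 and 3), 31 with a sex effect per state (11 higher, 20 lower), 5 with only these groups fitted, and 6 to 49 leaving out a mouse. With the NK covariate they were 9 and 10, and Dusp2 at rest stood at -1.93. For activation in control leaving out a mouse gave 6981 to 10646 genes, and a minimum fold of 2 gave 4136 there and 4647 in cKO. The interaction (0) gave 39 without the filter, 17 with DESeq2 and 0 to 3 leaving out a mouse.

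Lists called at rest (10) numbered 0 with an estimated correlation, 0 by fry, 3 to 12 leaving out a mouse and 2 with the NK covariate, both lower. After activation (10) they numbered 1, 1 and 6 to 15, and 7 with the NK covariate. In the activation comparisons (20 each) they numbered 7 and 6 with an estimated correlation and 27 in each by fry. For the interaction (4) they numbered 0 with an estimated correlation, 0 by fry, 1 without sex, 2 without the filter and 3 to 11 leaving out a mouse. In the cytokine list after activation the estimated correlation gave an adjusted p of 0.0416 with DESeq2 size factors, 0.196 without sex and 0.207 with the mouse number as a block.

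For the pairing by animal, the block gave 10352 and 11840 genes for activation in control and cKO cells and 0 for the interaction, 20 lists in each activation comparison and 5 for the interaction, and changed no named call in these comparisons. Control and cKO mice of the same number are different animals, both male for number 1 and of different sex for number 2. Their deviations correlated at 0.22 and -0.17 at rest and 0.2 and -0.27 after activation. With sex removed the correlations were -0.15 and 0.15 at rest and -0.18 and 0 after activation. The number block took the place of the sex term and left cKO mouse 3 without a control mouse. With the number as a block Eomes passed at rest (adjusted p = 0.00388) and after activation (0.00378), and lists called numbered 7 and 8. In the interaction 26.9%, 79.1% and 97% of simulated changes of 0.5, 1 and 2 on the log2 scale were recovered. That simulation held many changed genes where the data gave 0, so recovery in the data can be lower. The part of depth alone was not tested.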

Other observations

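The tests around Dusp2 were chosen after the result was seen, as were the test of NK cells by Tyrobp and Fcer1g and the reading of the NK marker covariate by the share of Eomes; the tests on chromosome 16, memory genes and splits were written before their results. Sex, taken as a term in the fit, changed 771 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 235 higher and 536 lower in female mice. That term sets 2 female against 3 male mice, and each mouse enters with 2 libraries. The fit counts these 2 libraries as independent although sex varies only between mice, so the p-values for sex can be too small. The genotype comparisons take 1 state at a time, so the counts are also not comparable in power. The second principal component, with 9.0% of the variance, separated male from female libraries, and the first, with 69.8%, activated from rested ones. Sex coincides with the number that starts the mouse names, so these counts belong to both.

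Interferon-stimulated genes moved in both directions on activation, with 21 of 55 higher and 15 lower in control and 23 and 16 in cKO cells, also 21 and 15, and 23 and 18, adjusted over the list alone. Irgm1, an interferon-induced GTPase gene, rose 5.91-fold and 5.47-fold. Camera's adjusted p were 0.000388 and 0.00271, and adjusted p = 0.303 and 0.338 with an estimated correlation. Of 24 cholesterol genes 14 rose and 3 fell in control and 14 and 2 in cKO cells, also adjusted over the list alone (adjusted p = 0.508 and 0.457 with an estimated correlation). Of 34 nuclear-encoded oxidative phosphorylation genes 28 rose and 2 fell in control and 29 and 1 in cKO cells (29 and 2, and 29 and 1, adjusted over the list alone), with Uqcrq, a complex III subunit, up 3.27-fold and 3.41-fold (adjusted p = 0.371 and 0.338 with an estimated correlation for the list). Of 22 glycolysis genes 14 rose and 6 fell in each genotype, also adjusted over the list alone (adjusted p = 0.433 and 0.45 with an estimated correlation). The lactate transporter gene Slc16a1 rose 3.55-fold and 3.65-fold, while Pdk1, a pyruvate dehydrogenase kinase gene, fell 2.90-fold and 2.95-fold. T cell receptor signalling genes fell more often than they rose, 17 against 10 of 30 in control and 19 against 9 in cKO cells, also adjusted over the list alone, but the list was not called (camera adjusted p = 0.0893 and 0.0721). Cd74, the invariant chain of MHC class II, a B cell marker in its list, rose 40.2-fold and 44.1-fold to 31.7 ± 4.9 CPM and 29.8 ± 7.9 CPM (n = 2 and 3), while that list was not called (adjusted p = 0.567 and 0.643).

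Astl, Adra2b and Gpat2, the genes that follow Dusp2 on its strand, were near absent in control cells and summed to 342 ± 31.0 CPM in rested and 802 ± 83.3 CPM in activated cKO cells. DNA of another strain around the floxed allele is argued against, since controls carry that allele and the lowest cKO library lay 8.71 above the highest control library on the log2 scale. A response to the missing protein by genes anywhere in the genome is argued against as well: the genes higher at rest formed 2 clusters, and the chance that either of 2 random places lies as near to Dusp2 as the farthest of the 3 genes, with 6 tested genes that near, is 0.000633; a response acting at the Dusp2 locus itself was not tested. Transcription running on from Dusp2 is a candidate explanation. Within 200 kb, 0 genes called higher lay upstream or on the opposite strand, which restates where the 3 genes lie. Their summed level rose by 1.23 (SD 0.03, n = 3 mice) on the log2 scale on activation, where Dusp2 in control cells rose by 1.67. In cKO cells 5976 genes rose on activation, so this rise is weak evidence. The sum lay above Dusp2 itself, in CPM not scaled by gene length. Dusp2 stood at 92.6 and 295 CPM in rested and activated control cells and at 26.0 and 51.8 CPM in cKO cells. Running on stays a hypothesis, because the deleted part of the gene is not given in the sources used here and gene totals do not show reads between genes.

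On chromosome 16, 1810053B23Rik, 1700029J03Rik and Gm30695 were present in cKO cells and near absent in control cells of both states. Of 82 tested genes within 5 Mb on either side, 10 (12.2%, exact 95% interval 6.01 to 21.3%) had an unadjusted p below 0.05 at rest, against 4.08% of other genes (1-sided Fisher's exact test p = 0.00193). After activation it was 9 of them (11% against 5.98%). This is consistent with DNA of another strain carried along with the cre transgene, which only the cKO mice have, though neighbouring genes are not independent. An enhancer brought in at that place cannot be told apart from it: 0 tested genes between the outer 2 had a fold change under 2, but with 3 tested genes in the interval that test could hardly come out otherwise.

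The cytokine and chemokine list was higher in activated cKO cells, at 1070 ± 51.3 CPM summed against 866 ± 28.1 CPM in control. More NK cells are argued against: Tyrobp and Fcer1g, abundant transcripts of NK cells, summed to 0.65 ± 0.10 CPM against 0.607 ± 0.325 CPM (0.548 ± 0.085 CPM against 0.88 ± 0.016 CPM at rest), and the gap of 129 CPM in the list, from the lowest cKO to the highest control library, was 174 times their highest level in an activated cKO library. Other innate-like cells stay open: with the summed NK and innate-like markers as a covariate the list's median log2 fold change went from 0.68 to 0.20 (camera adjusted p = 0.00862; p = 0.0261 with an estimated correlation, before adjustment), but Eomes, which CD8+ T cells also express, held 75.8% of that marker level in activated cKO and 71.4% in activated control cells (62.4% and 52% at rest). Trdc, of gamma delta T cells, was at 5.25 ± 0.26 CPM against 5.21 ± 0.01 CPM after activation (log2 fold change -0.00, SE 0.12) and Zbtb16, of NKT cells, at 0.661 ± 0.296 CPM against 0.738 ± 0.211 CPM (-0.32, SE 0.41), which goes against these cells without excluding them. More memory-phenotype cells among the cKO T cells may also account for the higher list: 23 of 24 memory genes were positive at rest (mean 0.53, SE over genes 0.07; camera p = 1.38e-12), but with an estimated correlation p was 0.0962, so the test does not decide, and 6 of these genes are in the cytotoxic and 4 in the effector transcription factor list.

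For activation in cKO cells, the real split of the 6 libraries gave 10992 genes when fitted alone without sex, and the highest of the other splits gave 0. The real split was the only 1 of 10 splits as large, and 10 splits are too few for a share under 0.05. Of the others, 3 also parted the libraries of every mouse, and each of these mixed both states.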
